A study of Mus musculus with 60 samples.

How the data were processed

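Total RNA of 5 mouse cell lines was hybridised to spotted 2-colour arrays, per the labels. IM2 is the untransfected line, WTA and WTD carry wild-type Pabpn1 at a level labelled high and low, and D7E and D7F carry mutant Pabpn1 at a level labelled high and low. Each line was grown as 3 cultures. The RNA of each culture was hybridised against 1 common IM2 reference on 2 array parts that carry different probes, and on each part with both dye orientations. This made 4 arrays per culture and 60 arrays in all, 30 per part. Groups, culture numbers and dyes were taken from the array titles and channel sources. For WTA culture 3 on part I the titles and the channel sources disagree on the dye, and the channel sources were used. The description of 1 part I array of D7F culture 1 calls its level high, while its title and the other arrays of that line do not, and the title was used.

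The deposited values are log ratios, with no unit stated. The base was taken to be 10 (log10) because the deposited values stop exactly at -2 and 2, which is a ratio of 100 in base 10 and would be a ratio of 4 in base 2. Values were multiplied by 3.3219 to give log2 ratios. Every size on the log2 scale and every fold printed here therefore holds only if the base is 10, while signs, calls and ranks do not depend on it. Scanning, background correction, normalisation and the rule behind the limits are not given in the sources used here, and no spot intensities were used. Pabpn1 had a positive ratio on 24 of 24 part I arrays of the transfected lines, whichever dye carried the culture RNA. All deposited ratios were therefore read as culture over reference, with no sign turned. The direction of part II has no such marker. For 156 genes measured on both parts, the differences between transfected lines and IM2 correlated across genes with r = 0.3965, and 7 of 8 genes called on both parts had the same sign. Genes are not independent replicates in such a correlation. The IM2 arrays have no Pabpn1 difference from the reference that would show their direction, so all fits were repeated with the sign of every IM2 array turned.

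Of the filled values, 7.98% on part I and 11.2% on part II lay at a limit. They were treated as not measured, a choice made after the data were examined, and the fits were repeated with them kept. Arrays differed in quality. The share of filled rows was 82.4% to 99.9% on part I and 46.0% to 99.4% on part II, and the share of filled values at a limit was 0.721% to 28.7% and 2.76% to 33.2%. The median log2 ratio of an array, over values inside the limits, was -0.41 to 0.39 on part I and -0.28 to 0.23 on part II. The 2 dye orientations of 1 culture correlated over probes with a median r of 0.1245 in the transfected cultures on part I (-0.1189 to 0.2506) and 0.1138 on part II (-0.0062 to 0.1795). In the IM2 cultures these correlations were -0.3492 to -0.175 on part I and -0.096 to 0.0119 on part II. Turning the sign of all IM2 arrays leaves these values as they are. It therefore cannot show whether 1 orientation is reversed against the other. Between arrays of 1 orientation the lowest correlation was -0.2494 with the limit values left out (IM2 culture 1 with D7E culture 3, part I). With the limit values kept, 4 pairs on part I and 6 on part II lay under -0.3, the lowest at -0.4784 (IM2 culture 1 with D7E culture 3, part I). The dyes are stated in the labels and the lines could differ in opposite ways, so the direction was kept. The number of arrays limits the precision, and no depth can be given for ratios.

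Part I has 16416 rows, which hold 7600 distinct probes after rows with identical values were collapsed, and part II has 15552 rows with 14326 distinct probes. On part I, 6722 probes had 1 gene symbol matched by Entrez identifier to the mouse gene table of assembly GRCm38.p6, which was used for names only. Another 29 kept the name in the platform annotation, 730 had no symbol and 7 had several. On part II these numbers were 9239, 644, 4200 and 114. Control probes were left out (109 with a human symbol and 3 unnamed on part I, 112 and 17 on part II). A culture's value was the mean of its 2 dye orientations, and both were required. Probes measured in at least 2 cultures of every line were tested, 4650 on part I and 5053 on part II, which makes 9703 probes for 8107 genes.

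Each part was fitted on its own with limma (version 3.58.1 in R 4.3.3; lmFit and eBayes), with all 5 lines in 1 model and the culture as the unit. Benjamini-Hochberg adjustment ran over both parts together for each comparison, with a threshold of 0.05. The comparisons were each transfected line against IM2, the mean of the 4 transfected lines against IM2, D7E against WTA, D7F against WTD, mutant against wild-type, high against low, and the genotype by level interaction, which is given as the mean of WTD and D7E minus the mean of WTA and D7F. The p-values measure the spread between cultures of the same line. Each genotype and level is represented by 1 line, so a difference between genotypes or levels is also a difference between lines. Shifts of 24 gene lists, fixed before the data were examined, were tested with camera in its form for ready-made statistics (cameraPR), since the parts were fitted separately. It ran on the z-scores of the fit with a preset correlation of 0.01 between genes and 1 probe per gene. Benjamini-Hochberg adjustment ran over the lists of a comparison. An alternative with a correlation estimated from the data also used a t distribution with fewer degrees of freedom. A list call lost in that alternative need not be lost through the correlation alone. The genes named in the text were chosen by a rule also fixed before the data were examined. It takes Pabpn1 first. For each comparison against IM2, for high against low and for the interaction it takes the 6 largest rises and the 6 largest falls that passed the threshold, and for the comparisons of mutant with wild-type the 8 largest of each. These genes had to be measured in all 3 cultures of the lines compared, with no overlap between the cultures of both sides (not asked for the interaction). From each list with a called shift it takes the 4 members with the smallest adjusted p in the direction of the shift. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

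The fit was tested on simulated data with 200 of 9703 probes changed. The simulated noise was normal and independent, and each probe had the same spread in every culture, as the fit assumes. The real arrays differed in spread, which was 0.0841 to 0.343 on part I (from the quartiles, log10 scale). The false calls in the simulation therefore do not measure those in the real data. For WTA against IM2, 87.9% of the probes changed by 2 on the log2 scale were recovered, 62.7% of those changed by 1 and 4.48% of those changed by 0.5, with 6 false calls among 109. For transfected against IM2 these shares were 97.0%, 58.2% and 19.4% with 8 false calls among 124, for D7F against WTD 92.4%, 55.2% and 8.96% with 3 among 107, and for mutant against wild-type 93.9%, 80.6% and 28.4% with 9 among 144. For high against low they were 100%, 85.1% and 40.3% with 16 among 166, and for the interaction 97.0%, 80.6% and 19.4% with 4 among 135.

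Alternatives planned before the data were examined were the culture number as a block, centring and scaling of the arrays, each dye orientation alone, either orientation accepted, complete probes only, arrays as units with a dye term, only the lines compared, adjustment within each part, the titles' dye for WTA culture 3, the D7F array with the conflicting description left out, each culture left out in turn, the line as a random block, an estimated correlation or the mean over probes for the lists, the ratio to the reference tested against 0, and an adjusted p under 0.01. Added after the data were examined were the limit values kept, the arrays with many values at the limit or missing left out (a culture then counted with its other array), the sign of the IM2 arrays turned, and the titles' dye for WTA culture 3 joined with each orientation alone.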

Results

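Gene expression was compared between 5 mouse cell lines on 2-colour microarrays. The IM2 line was untransfected. WTA and WTD carried wild-type Pabpn1, with WTA labelled high and WTD labelled low, and D7E (high) and D7F (low) carried mutant Pabpn1. Pabpn1 encodes the nuclear poly(A)-binding protein, which binds the poly(A) tails of RNA in the nucleus. The labels name oculopharyngeal muscular dystrophy (OPMD), a muscle disease caused in people by an expanded alanine stretch in this protein. The labels do not say which mutation the mutant lines carry, nor from which tissue the lines came. The plan nevertheless took the lines to come from muscle when markers of other cell types were chosen. Each line was represented by 3 cultures, and each culture by 4 arrays against 1 common IM2 reference, 2 dye orientations on each of 2 array parts. In all, 60 arrays and 15 cultures were analysed. Values are log2 ratios of culture over reference, on the assumption that the deposited log ratios have base 10, and 9703 probes for 8107 genes could be tested. Across probes, the 3 cultures of a transfected line correlated with r = 0.416 to 0.591 for WTA, 0.614 to 0.645 for WTD, 0.526 to 0.59 for D7E and 0.445 to 0.563 for D7F. The IM2 cultures correlated with r = 0.0233 to 0.0751. Theirs are ratios of IM2 RNA over an IM2 reference, where the design leaves little difference to correlate. The low r is therefore no measure of how well the IM2 cultures agree. Probes are not independent replicates in these correlations. The number of arrays limits the precision of every value.

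Pabpn1 itself was higher in all 4 transfected lines than in IM2, and higher in the lines labelled high than in those labelled low. Its mean log2 ratio was -0.18 ± 0.06 (SD, n = 3) in IM2, 2.19 ± 0.29 in WTA, 1.43 ± 0.07 in WTD, 1.61 ± 0.14 in D7E and 0.92 ± 0.11 in D7F, with n = 3 in each. Against IM2, Pabpn1 rose by 2.37 in WTA (SE 0.14, adjusted p = 3.76e-06), which is 5.17-fold. It rose by 1.61 in WTD (adjusted p = 7.72e-05), by 1.79 in D7E (adjusted p = 7.96e-05) and by 1.09 in D7F (adjusted p = 0.00122; limma with Benjamini-Hochberg adjustment). The high lines exceeded the low lines by 0.73 (SE 0.10, adjusted p = 0.00575). The mutant lines had less Pabpn1 signal than the wild-type lines, by a difference of -0.55 (SE 0.10) that did not pass the threshold (adjusted p = 0.055). The difference between D7E and WTA was -0.58 (adjusted p = 0.0567) and that between D7F and WTD was -0.52 (adjusted p = 0.201), while the interaction of genotype and level was -0.03 (adjusted p = 0.926). The difference of Pabpn1 in high vs low did not pass with the arrays centred and scaled (0.061, adjusted p = 0.968), with the line as a random block (adjusted p = 0.392), with Cy5 arrays alone (adjusted p = 0.162) or without the 10 arrays that had many values at the limit or missing (adjusted p = 0.097). Over its alternatives, Pabpn1 in mutant vs wild-type had adjusted p = 0.00418 to 0.996, and it passed in 5 settings, among them the arrays centred on their medians (adjusted p = 0.0276) and the fit without culture 3 of WTA (adjusted p = 0.00867). Pabpn1 in D7E vs WTA ranged from adjusted p = 0.0152 to 0.881 and also passed in 5 settings, among them the arrays centred (adjusted p = 0.0452) and the fit without culture 3 of WTA (adjusted p = 0.0214). The labels do not say whether the probe detects the endogenous transcript, the transfected one or both.

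**Figure D1:**
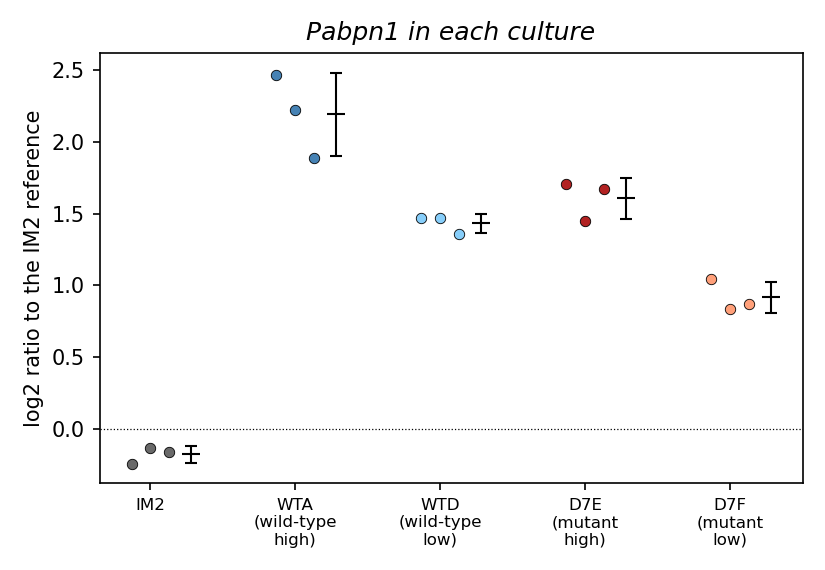
Log2 ratio of Pabpn1 in each culture over the common IM2 reference, by line. Points are cultures, bars show the mean with its SD (n = 3 cultures), and the dotted line marks a ratio of 1. The WTA mean of 2.19 is the highest and the D7F mean of 0.92 the lowest among the transfected lines, while IM2 lies at -0.18.

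To ask what the transfected lines had in common, their mean was compared with IM2. The lists of the endoplasmic reticulum stress response, the cell cycle and the interferon response were lower, while those of sarcomere proteins and proteasome subunits were higher. Among genes measured in all 15 cultures, with no overlap between the IM2 and the transfected cultures, the largest falls were those of Ndrg1, a stress-responsive gene (-2.88 on the log2 scale, SE 0.17, adjusted p = 7.05e-06, and -1.99 for a second probe), and Adm, which encodes the vasodilator peptide adrenomedullin (-2.62, SE 0.20, adjusted p = 2.15e-05). Ero1a, an oxidase of the endoplasmic reticulum, followed with -2.47 (SE 0.18, adjusted p = 1.31e-05). Arrdc4 changed by -2.33, Crisp2 by -1.97 and the collagen gene Col11a1 by -1.93 (highest adjusted p = 0.000137). After Pabpn1 (1.71, SE 0.11, adjusted p = 7.05e-06), the largest rises among these genes were those of Bex2 (1.56, SE 0.17, adjusted p = 0.000113) and Actr1a, a dynactin subunit (1.51, SE 0.18, adjusted p = 0.00028). Rb1, the retinoblastoma protein that restrains the cell cycle, rose by 1.45 (SE 0.22, adjusted p = 0.00127). Bex1 rose by 1.31 (SE 0.14, adjusted p = 0.000137). Sh2d2a also rose by 1.31 (adjusted p = 0.0152), a call that ended without culture 1 of IM2 (adjusted p = 0.0732). The IM2 cultures themselves lay at -0.76 for Actr1a, and with the sign of the IM2 arrays turned the Actr1a difference was -0.0026. In total 1479 of 9703 probes passed, 622 higher and 857 lower in the transfected lines, and 2975 had an unadjusted p under 0.05 (limma with Benjamini-Hochberg adjustment). The count was 802 without culture 1 of IM2, 884 without culture 3 of IM2, and 502 without the 10 arrays that had many values at the limit or missing, where the cultures concerned counted with their other array and 12170 probes were tested.

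Among the lists that were lower in the transfected lines, the endoplasmic reticulum stress response had 16 of 32 measured members that fell and 0 that rose (17 and 0 adjusted over the list alone). Its median was -0.38 (camera, adjusted p = 3.15e-09). Ddit3, the stress transcription factor also called CHOP, fell by 1.72 (SE 0.12, adjusted p = 1.1e-05), its target Trib3 fell by 1.18 and P4hb, a protein disulfide isomerase, fell by 1.39. Of 50 cell cycle genes 16 fell and 0 rose (25 and 1 adjusted over the list alone; median -0.40, adjusted p = 6.15e-07). They included Cdt1, a factor that licenses replication origins, which fell by 1.88 (SE 0.21, adjusted p = 0.000113), Cks2, which fell by 1.23, and Rrm2, a subunit of ribonucleotide reductase, which fell by 0.98. Of 32 genes of the interferon response and antigen presentation 14 fell and 1 rose (15 and 1 adjusted over the list alone; median -0.42, adjusted p = 3.82e-06). Isg15, a ubiquitin-like interferon-induced protein, fell by 1.38 (SE 0.11, adjusted p = 3.19e-05) and the class I antigen gene H2-D1 fell by 1.15. Of 54 matrix genes 27 fell and 3 rose (28 and 6 adjusted over the list alone; median -0.58, adjusted p = 2.08e-07), a shift that did not pass with an estimated correlation between genes (adjusted p = 0.187). Among them were Lama4, a laminin chain that fell by 1.67, and Lox, a collagen cross-linking enzyme that fell by 1.36. Fibroblast markers moved with the matrix genes: 6 of 15 fell and 1 rose (7 and 1 adjusted over the list alone; median -0.44, adjusted p = 0.00251). The collagen genes led them, Col3a1 (-1.44, adjusted p = 0.000336) and Col1a1 (-1.22, adjusted p = 0.00161). The fibroblast list shares 7 of its 24 genes with the matrix list. The glycolysis list was lower as well (4 of 16 fell and 1 rose, 5 and 1 adjusted over the list alone; median -0.24, adjusted p = 0.00401; adjusted p = 0.23 with an estimated correlation), and its leading member Bnip3, which acts in mitophagy, fell by 1.77. Ribosomal protein genes shifted slightly (4 of 61 fell and 0 rose, 3 and 0 adjusted over the list alone; median -0.12, adjusted p = 0.00358; adjusted p = 0.389 with an estimated correlation), with Rpl28 falling by 0.57, a call that ended without the arrays with many values at the limit or missing. With an estimated correlation between genes, the stress, cell cycle, interferon and fibroblast lists each held with adjusted p = 0.0399.

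Among the lists that were higher, sarcomere proteins had 16 of 37 members that rose and 1 that fell (20 and 2 adjusted over the list alone), with a median of 0.48 (camera, adjusted p = 1.13e-07). Tmod4, which caps thin filaments, rose by 0.94 in the mean of the lines (SE 0.12, adjusted p = 0.000425), although its mean was -0.08 in WTD beside -0.04 in IM2. Lmod2 rose by 0.76, and the Z-disc genes Myoz1 and Myot by 0.73 and 0.71. Genes of muscle calcium handling and energy metabolism rose in 8 of 26 cases and fell in 0 (13 and 0 adjusted over the list alone; median 0.35, adjusted p = 0.000243; adjusted p = 0.187 with an estimated correlation). They included Fabp3, a fatty acid carrier (0.76), the calcium release component Trdn (0.68) and the glucose transporter Slc2a4 (0.67). Myogenic regulators and fusion genes had 11 of 29 members that rose and 3 that fell (15 and 3 adjusted over the list alone; median 0.34, adjusted p = 0.00401). Rb1 and Cdkn1c (0.69, adjusted p = 0.00247), both inhibitors of the cell cycle, led this list, followed by the muscle transcription factors Myf6 (0.54) and Mef2c (0.60). Cdkn1c did not move alike in the 4 lines: its means were 1.45 in WTD and 1.06 in D7E, but -0.30 in WTA and -0.32 in D7F beside -0.22 in IM2. Of 35 proteasome subunits 11 rose and 0 fell (17 and 0 adjusted over the list alone; median 0.28, adjusted p = 4.86e-07), for example Psmc5 (0.79, SE 0.13, adjusted p = 0.00205) and Psmd10 (0.45). Heat shock proteins and chaperones had 7 of 43 members that rose and 2 that fell (8 and 2 adjusted over the list alone; median 0.27, adjusted p = 0.00401; adjusted p = 0.187 with an estimated correlation), led by the co-chaperone Bag1 (0.66) and the small heat shock protein Cryab (0.55). Oxidative phosphorylation genes had a median of 0.20 (4 of 58 rose and 1 fell, 3 and 1 adjusted over the list alone; adjusted p = 0.00124, and 0.32 with an estimated correlation), with Ndufa4 at 0.57 and Atp5pb at 0.71. The sarcomere, myogenic and proteasome lists held with an estimated correlation, each with adjusted p = 0.0399. The ubiquitin list (8 of 57 rose and 2 fell, 8 and 2 adjusted over the list alone; median 0.19, adjusted p = 0.0356) had adjusted p = 0.189 with an estimated correlation. Its call ended without culture 2 or 3 of IM2, culture 1 of D7E or culture 3 of D7F, at an adjusted p of up to 0.102. The cholesterol synthesis list (3 of 15 rose and 1 fell, 4 and 1 adjusted over the list alone; median 0.36, adjusted p = 0.0356) had adjusted p = 0.187 with an estimated correlation. Its call ended without culture 2 or 3 of IM2, at an adjusted p of up to 0.0691. Ube2v2 (0.61, adjusted p = 0.0027) and Fdft1 (0.56, adjusted p = 0.00169) led these lists. Without the arrays with many values at the limit or missing, the calls of Rb1, Myf6, Mef2c, Slc2a4, Atp5pb and Fdft1 ended. With the sign of the IM2 arrays turned, those of Cdkn1c, Bag1 and Atp5pb did, and the call of the heat shock list.

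No shift passed for polyadenylation and poly(A) binding, the function of Pabpn1 (31 genes, median 0.04, adjusted p = 0.667; camera). Nor did one pass for splicing and hnRNP proteins (55 genes, median -0.02 and mean 0.03, adjusted p = 0.973) or for p53 targets and cell death (39 genes, median 0.08, adjusted p = 0.667). Among markers of other cell types, those of adipocytes had a median of 0.15 (11 genes, adjusted p = 0.0538), endothelial markers 0.38 (7 genes, adjusted p = 0.128) and neural and Schwann cell markers 0.19 (10 genes, adjusted p = 0.354). Smooth muscle markers had a median of 0.07 and a mean of -0.01 with a test pointing down (11 genes, adjusted p = 0.973). Leukocyte markers had a median of -0.13 and a mean of 0.03 (5 genes, adjusted p = 0.973) and bone and cartilage markers a median of -0.04 and a mean of 0.08 (4 genes, adjusted p = 0.973), both with a test pointing up. Beside these groups stands the quality of the IM2 arrays: 4 of the 10 arrays with many values at the limit or missing were of IM2, both part I arrays of culture 1 and 1 part II array each of cultures 2 and 3.

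**Figure D2:**
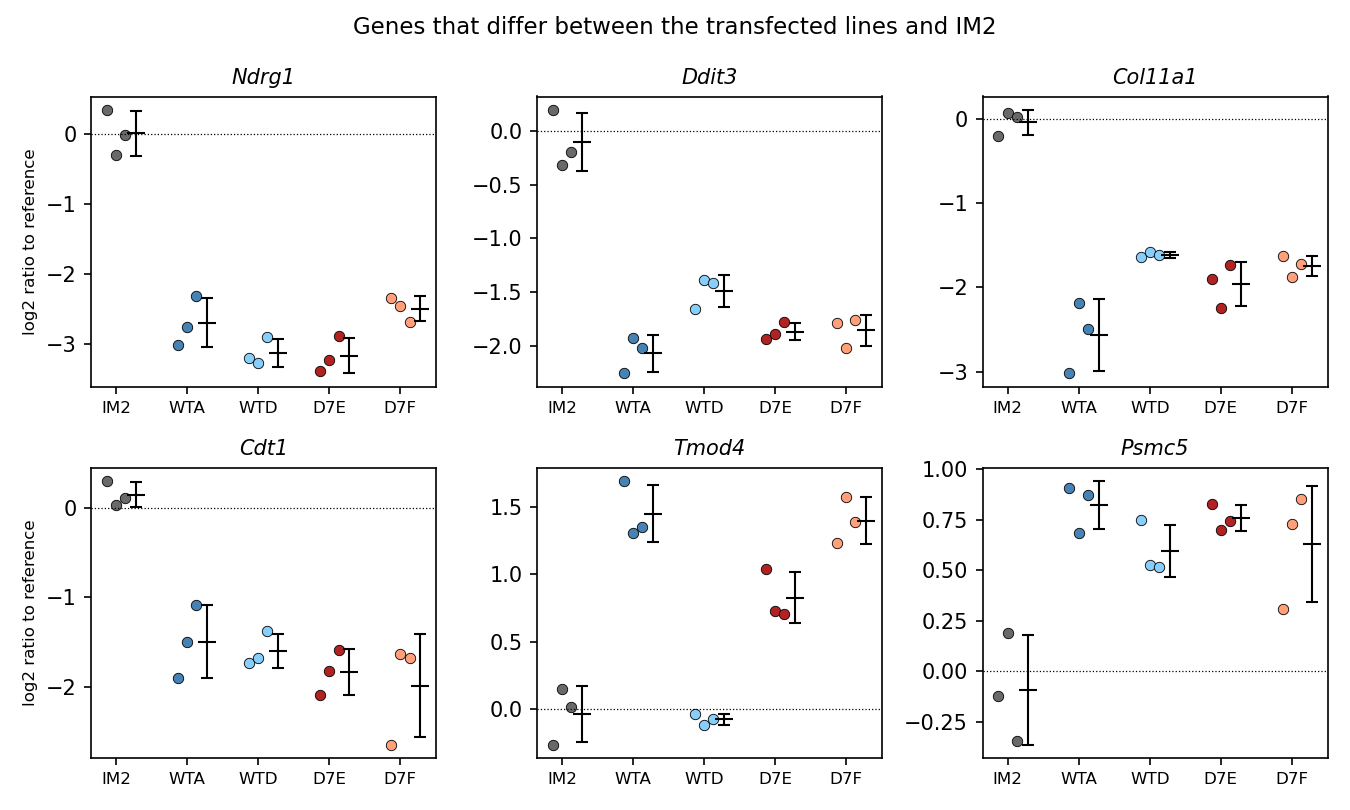
Log2 ratio over the IM2 reference for Ndrg1, Ddit3, Col11a1, Cdt1, Tmod4 and Psmc5 in each culture, by line. Points are cultures, bars show the mean with its SD, and the dotted line marks a ratio of 1. Ndrg1, Ddit3, Col11a1 and Cdt1 lie lower in the transfected lines than in IM2, with a difference of -2.88 for Ndrg1, and Tmod4 and Psmc5 lie higher, by 0.94 and 0.79 for the mean of the 4 lines, except that Tmod4 lies at -0.08 in WTD.

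**Figure D3:**
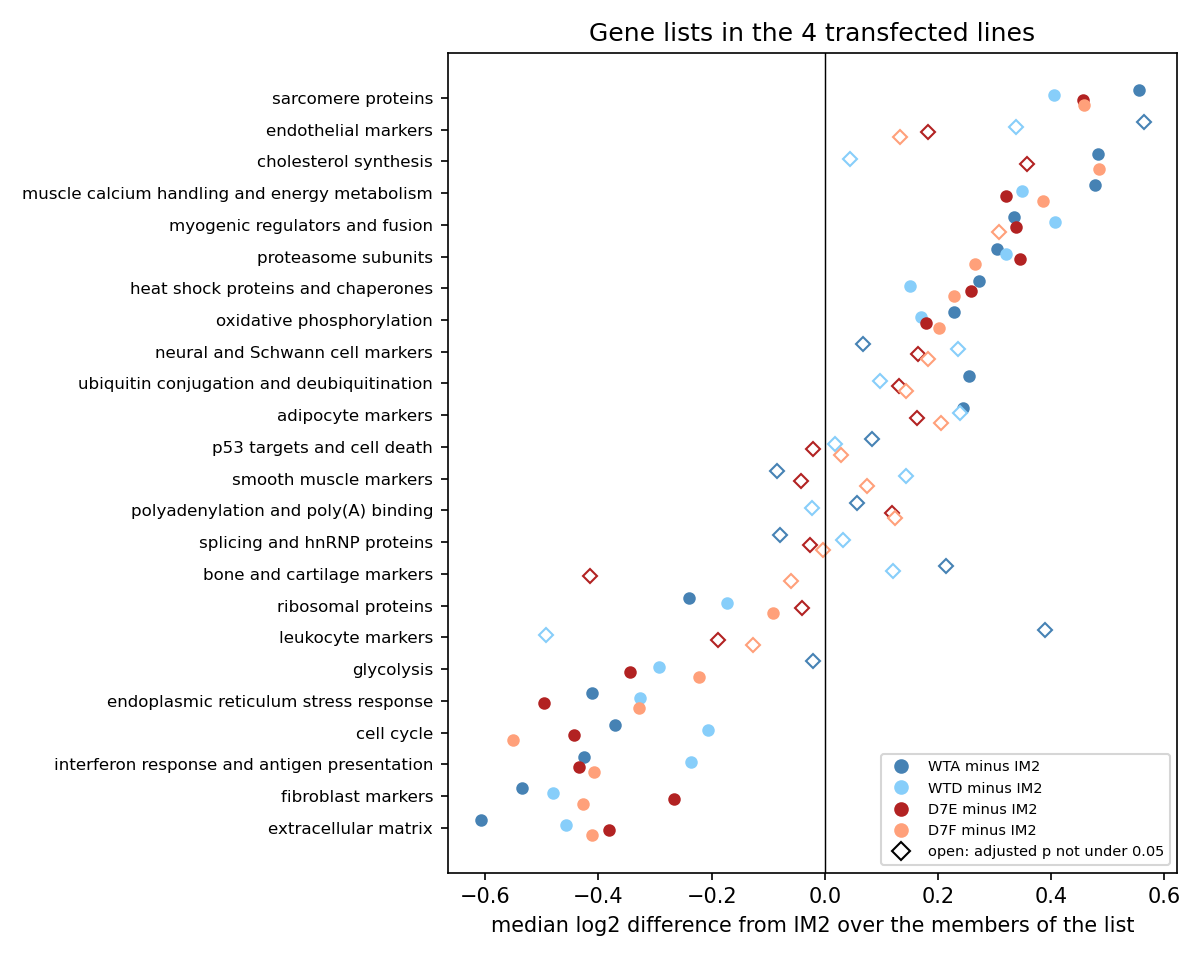
Median log2 difference from IM2 of each of 24 gene lists (1 per line of the vertical axis) in the 4 transfected lines; filled circles passed the test of the list at an adjusted p under 0.05 and open diamonds did not. The endoplasmic reticulum stress list lies between -0.50 (D7E) and -0.33 (WTD and D7F), and the sarcomere list between 0.40 (WTD) and 0.56 (WTA).

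Each line was also set against IM2 on its own. Among genes measured in all cultures compared, with no overlap between them, Ndrg1 and Ero1a were among the 6 largest falls in every line. Ndrg1 differed by -2.70 (SE 0.21, adjusted p = 2.95e-05) in WTA, -3.14 (adjusted p = 2.16e-05) in WTD, -3.18 (adjusted p = 3.72e-05) in D7E and -2.51 (adjusted p = 0.000126) in D7F. A second Ndrg1 probe differed by less, -2.05 in WTA, -2.46 in WTD, -2.04 in D7E and -1.40 in D7F. In WTA, 502 probes rose and 619 fell, 1121 in all with 2634 at an unadjusted p under 0.05 (limma with Benjamini-Hochberg adjustment). Actr1a rose by 2.48 (SE 0.23, adjusted p = 9.21e-05), Magef1 by 2.30 (SE 0.47, adjusted p = 0.00798) and Sohlh2, a germ cell transcription factor, by 1.95 (SE 0.34, adjusted p = 0.00343). For Actr1a the mean was 1.72 in WTA and -0.76 in IM2, so its size rests in part on the direction of the IM2 arrays. Tcstv1 changed by -3.08 (SE 0.31, adjusted p = 0.000175), Ero1a by -2.67, Col11a1 by -2.53 and Tfpi2, a protease inhibitor of the matrix, by -2.22 (adjusted p = 0.000121). Snrpb, a core splicing protein, rose by 1.97 (adjusted p = 0.0145), with the IM2 cultures at -1.37, and differed by -0.77 with the sign of the IM2 arrays turned. The calls for Tcte3 (2.03, adjusted p = 0.0361) and Tenm3 (-2.38, adjusted p = 0.0472) each ended without single cultures, at an adjusted p of up to 0.0965 without culture 1 of WTA and 0.101 without culture 2 of IM2. Tcte3 differed by -0.17 with the sign of the IM2 arrays turned. The WTA count was 380 with the arrays centred and scaled and 14 when WTA and IM2 alone were fitted. It was 712 without culture 1 of IM2, 581 without culture 1 of WTA, and 413 without the arrays with many values at the limit or missing.

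In WTD, 202 probes rose and 480 fell, 682 in all with 2230 at an unadjusted p under 0.05 (limma with Benjamini-Hochberg adjustment). Gpx7, a peroxidase of the endoplasmic reticulum, changed by -3.37 (SE 0.23, adjusted p = 8.46e-06), Adm by -3.22 (SE 0.26, adjusted p = 6.86e-05), Arrdc4 by -2.67, Ero1a by -2.41 and Bnip3 by -2.40 (adjusted p = 7.45e-05). The gene 3830403N18Rik rose by 2.19 (SE 0.38, adjusted p = 0.00414) and the potassium channel subunit Kcnmb4 by 1.75 (SE 0.25, adjusted p = 0.00205). Cdkn1c rose by 1.67 (SE 0.15, adjusted p = 7.72e-05), and Myl2, a regulatory myosin light chain of slow muscle and heart, by 2.11 (SE 0.33, adjusted p = 0.00296). A probe of Xlr rose by 1.90 (adjusted p = 0.00188), while a second Xlr probe differed by -0.19. Trabd rose by 2.19 (adjusted p = 0.00013) with the IM2 cultures at -1.98, and differed by -1.78 with the sign of the IM2 arrays turned. The WTD count was 1142 with the arrays centred and scaled and 227 when WTD and IM2 alone were fitted. It was 357, 1038 and 341 without cultures 1, 2 and 3 of IM2, 392, 364 and 297 without cultures 1, 2 and 3 of WTD, and 198 without the arrays with many values at the limit or missing.

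In D7E, 400 probes rose and 797 fell, 1197 in all with 2555 at an unadjusted p under 0.05 (limma with Benjamini-Hochberg adjustment). Kcnmb4 rose by 2.63 (SE 0.25, adjusted p = 0.000184), the protocadherin Pcdh7 by 1.66 (SE 0.35, adjusted p = 0.0103), Actr1a by 1.62 and the fucosyltransferase Fut8 by 1.61 (SE 0.34, adjusted p = 0.0103). The IM2 cultures lay at -0.54 for Pcdh7, -0.76 for Actr1a and -0.73 for Fut8, beside D7E means of 1.12, 0.86 and 0.88. The sizes of these rises therefore rest in part on the direction of the IM2 arrays. Adm changed by -3.22 (SE 0.26, adjusted p = 7.96e-05), Ero1a by -2.54, Arrdc4 by -2.51, the fatty acid carrier Fabp5 by -2.44 (SE 0.32, adjusted p = 0.00104) and Crisp2 by -2.43. Ube2c, which acts with the anaphase-promoting complex, fell by 2.06 (adjusted p = 0.000297) and the DNA polymerase subunit Pola1 by 1.78 (-1.78, adjusted p = 0.000486). Snrpb rose by 1.61 (adjusted p = 0.0339), but the call ended without any of 5 single cultures (adjusted p up to 0.0935, without culture 1 of D7E) or with the culture number as a block, and the difference was -1.13 with the sign of the IM2 arrays turned. The IM2 cultures 1, 2 and 3 lay at -2.63, -0.09 and -1.40 for Snrpb. Its size, here and in the other lines, therefore depends on culture 1 of IM2. The D7E count was 348 when D7E and IM2 alone were fitted. It was 781, 772 and 785 without cultures 1, 2 and 3 of D7E, 768 and 773 without cultures 1 and 3 of IM2, and 333 without the arrays with many values at the limit or missing.

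In D7F, 155 probes rose and 283 fell, 438 in all with 2008 at an unadjusted p under 0.05 (limma with Benjamini-Hochberg adjustment). Bex2 rose by 1.81 (SE 0.22, adjusted p = 0.000842), Tmod4 by 1.43 (SE 0.15, adjusted p = 0.000602) and Bex1 by 1.42 (SE 0.18, adjusted p = 0.00111). Arrdc4 changed by -2.67 (SE 0.24, adjusted p = 0.000126), 3830403N18Rik by -2.53 (SE 0.38, adjusted p = 0.00226), Ero1a by -2.27, Cdt1 by -2.14 and Mcm3, a subunit of the replicative helicase, by -2.07 (SE 0.33, adjusted p = 0.00683). Rb1 rose by 1.42 (adjusted p = 0.0123), Sohlh2 by 1.52 (adjusted p = 0.0227) and Snrpb by 1.78 (adjusted p = 0.0409). These 3 calls ended without single cultures, at an adjusted p of up to 0.0574 for Rb1 (without culture 2 of D7F), 0.0957 for Sohlh2 (without culture 1 of IM2) and 0.112 for Snrpb (without culture 1 of D7F). The Snrpb call also ended with the culture number as a block, and the difference was -0.96 with the sign of the IM2 arrays turned. The D7F count was 83 when D7F and IM2 alone were fitted and 708 with the sign of the IM2 arrays turned. It was 286, 207 and 266 without cultures 1, 2 and 3 of D7F, 239 and 762 without cultures 1 and 2 of IM2, and 137 without the arrays with many values at the limit or missing.

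The sarcomere, calcium and energy, proteasome, heat shock and oxidative phosphorylation lists were higher, and the stress, cell cycle, interferon, matrix and fibroblast lists lower, in every transfected line against IM2 (camera, adjusted p under 0.05 in each). Of all the calls of the 4 lines, only the cell cycle list of D7F (15 of 50 fell, 21 adjusted over the list alone; median -0.55) held with an estimated correlation (adjusted p = 0.026), and the others then had adjusted p = 0.0522 to 0.516. The sarcomere median was 0.56 in WTA (16 of 37 rose and 1 fell, 21 and 1 adjusted over the list alone), 0.40 in WTD (3 and 0, 12 and 2 adjusted over the list alone). It was 0.46 in D7E (11 and 2, 13 and 2 adjusted over the list alone) and 0.46 in D7F (8 and 0, 10 and 0 adjusted over the list alone). The stress list had medians of -0.41, -0.33, -0.50 and -0.33 in the same order, with 15, 10, 13 and 11 members that fell and 0 that rose (16, 13, 16 and 14 fell adjusted over the list alone, and 1 rose in WTA). The myogenic list was higher in WTA, WTD and D7E (adjusted p = 0.0472, 0.000285 and 0.00764), and in D7F it had adjusted p = 0.0592. The glycolysis list was lower in WTD, D7E and D7F and had adjusted p = 0.375 in WTA. Ribosomal genes were lower in WTA, WTD and D7F and had adjusted p = 0.287 in D7E. The cholesterol list was higher in WTA (adjusted p = 0.00407) and D7F (adjusted p = 0.00613). In WTA the ubiquitin list (adjusted p = 0.00661) and adipocyte markers (3 of 11 rose, median 0.24, adjusted p = 0.0463) were higher too, with the fatty acid transporter gene Cd36 at 1.29 (adjusted p = 0.000275). Single cultures ended the WTA calls of the myogenic list (adjusted p up to 0.112, without culture 3 of WTA) and the heat shock list (0.108, without culture 3 of WTA). In WTA they also ended those of fibroblast markers (0.0667, without culture 1 of IM2) and adipocyte markers (0.11, without culture 1 of IM2). The myogenic and adipocyte calls of WTA also ended with the culture number as a block. They also ended the ribosomal calls of WTD (0.0719, without culture 1 of IM2) and D7F (0.194, without culture 2 of D7F) and, in D7E, those of the calcium and energy list and oxidative phosphorylation (both 0.0546, without culture 1 of D7E).

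Calls were shared between lines in number. In all 4 lines 222 probes were called in the same direction, 48 higher and 174 lower, out of 1861 called in any line, and 12 were called in 2 or more lines with opposite signs. WTA and D7E shared 215 risen and 350 fallen probes, where independent lists of these lengths would share 20.7 and 50.8. WTD and D7E shared 141 and 404 (8.33 and 39.4 for independent lists), WTA and WTD 104 and 264 (10.4 and 30.6), and WTA and D7F 110 and 242 (8.02 and 18.1). D7E and D7F shared 108 and 246 (6.39 and 23.2), and WTD and D7F 71 and 201 (3.23 and 14.0). All lines were set against the same 3 IM2 cultures. Across genes, the differences of 2 lines from IM2 correlated with r = 0.713 to 0.813, beside 0.664 to 0.675 in 100 simulations of unchanged lines against those cultures, and their covariance was 0.186 to 0.216 beside 0.0935 to 0.0942, a difference of 0.0921 to 0.122. In these simulations a line had 3.49 calls on average, and 2 lines shared 2.72 to 2.87 in the same direction, at most 6. The shared controls alone thus gave few shared calls in unchanged lines. This does not show how much they add where lines do differ. Part of the excess over independent lists may therefore still come from the shared controls, which are too few to be split. The number of probes called in all 4 lines was 125, 475 and 146 without cultures 1, 2 and 3 of IM2. It was 144 and 129 without cultures 1 and 3 of WTD, 133 and 138 without cultures 2 and 3 of D7F, 7 with only the lines compared in each fit, and 58 without the arrays with many values at the limit or missing.

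D7E was compared with WTA to set mutant against wild-type Pabpn1 at the level labelled high. Padi2, which converts arginine to citrulline in proteins, was higher in D7E by 2.51 (SE 0.24, adjusted p = 0.00035), with line means of 0.61 in D7E and -1.90 in WTA. Kcnmb4 was higher by 2.49 (SE 0.25, adjusted p = 0.000524), Tcstv1 by 2.12 (SE 0.31, adjusted p = 0.00709) and the sodium channel gene Scn10a by 2.06 (SE 0.20, adjusted p = 0.00035). Dpep1, Spink4, Prr32 and Pacsin1 were higher by 1.66, 1.61, 1.48 and 1.43 (highest adjusted p = 0.00408). Myl2 fell by 1.92 (SE 0.30, adjusted p = 0.00791), Prelid2 by 1.32 (-1.32, adjusted p = 0.00651), Bnip3 by 1.29 (-1.29, adjusted p = 0.00933) and the glycolytic enzyme Pfkl by 0.91 (-0.91, adjusted p = 0.00893). The differences of Pias3 (-2.18), Sohlh2 (-1.55), Cav1 (-1.50), Adm (-1.21) and Ube2c (-1.19) passed, but each call ended without single cultures and with the culture number as a block. The highest adjusted p without a culture was 0.136 for Pias3, 0.127 for Sohlh2, 0.0957 for Cav1 and 0.134 for Ube2c (each without culture 2 of D7E) and 0.102 for Adm (without culture 1 of D7E). Glycolysis genes were lower in D7E (0 of 16 rose and 2 fell, 0 and 4 adjusted over the list alone; median -0.42, camera, adjusted p = 9.98e-05; adjusted p = 0.612 with an estimated correlation). Ribosomal protein genes were higher (0 of 61 passed singly, 0 adjusted over the list alone; median 0.21, adjusted p = 9.98e-05; adjusted p = 0.612 with an estimated correlation). In total 159 probes passed, 60 higher and 99 lower in D7E, with 1424 at an unadjusted p under 0.05 (limma with Benjamini-Hochberg adjustment). With the arrays centred and scaled the split was 33 higher and 100 lower. The count was 96, 52 and 66 without cultures 1, 2 and 3 of D7E, and 50 without culture 1 of WTA. It was 77, 87 and 100 without those of D7F, 82, 68 and 71 without those of WTD, and 48 without the arrays with many values at the limit or missing. It was 2 when D7E and WTA alone were fitted and 75 with the culture number as a block. The calls of Kcnmb4, Spink4, Prelid2 and Pfkl ended without the arrays with many values at the limit or missing, and those of Bnip3 and Pfkl with the arrays centred and scaled.

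D7F was compared with WTD to set mutant against wild-type Pabpn1 at the level labelled low. Gpx7 was higher in D7F by 3.02 (SE 0.23, adjusted p = 2.43e-05), with line means of -0.35 in D7F and -3.38 in WTD. Pvalb, the calcium buffer of fast muscle, was higher by 2.27 (SE 0.17, adjusted p = 2.48e-05), the carboxylesterase Ces2g by 2.19 (SE 0.18, adjusted p = 2.48e-05) and Tmod4 by 1.47 (SE 0.15, adjusted p = 0.00055). The gene 3830403N18Rik fell by 4.72 (SE 0.38, adjusted p = 2.43e-05), from a mean of 2.35 in WTD to -2.37 in D7F, which was the largest difference named in any comparison. Lrrn1 differed by -2.33 (SE 0.17, adjusted p = 2.43e-05; a second Lrrn1 probe by -0.49), Cdkn1c by -1.77 (SE 0.15, adjusted p = 6.29e-05), Scn10a by -1.44 (SE 0.20, adjusted p = 0.00652) and Prr32 by -1.29 (SE 0.15, adjusted p = 0.00069). A probe of Xlr differed by -2.61 (adjusted p = 0.00055) and a second Xlr probe by 0.01. Eml1 (1.75), Tgfbi (1.29), Mss51 (1.19), Ano10 (1.18), Nmrk2 (-1.36) and Sln (-1.17), an inhibitor of the muscle calcium pump, passed, but each call ended without single cultures, and that of Eml1 also with the culture number as a block. The highest adjusted p without a culture was 0.166 for Eml1 and 0.116 for Tgfbi (without culture 2 of D7F), 0.0799 for Mss51 (without culture 1 of WTD), and 0.106 for Ano10 and 0.0699 for Nmrk2 and Sln (without culture 2 of WTD). In total 44 probes passed, 23 higher and 21 lower in D7F, with 704 at an unadjusted p under 0.05 (limma with Benjamini-Hochberg adjustment). The count was 102 with the arrays centred and scaled and 29 when D7F and WTD alone were fitted. It was 18 and 24 without cultures 2 and 3 of D7F, 15, 23 and 19 without cultures 1, 2 and 3 of WTD, and 23 without the arrays with many values at the limit or missing.

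Cell cycle genes were lower in D7F than in WTD (0 of 50 passed singly and 3 fell adjusted over the list alone; median -0.25, camera, adjusted p = 4.22e-10), and this held with an estimated correlation (adjusted p = 0.0274). Ube2c differed by -1.20 (adjusted p = 0.0507) and Pola1 by -0.83 (adjusted p = 0.0923). Cholesterol synthesis genes were higher (1 of 15 rose and 0 fell, 3 and 0 adjusted over the list alone; median 0.35, adjusted p = 0.000198), with adjusted p = 0.0502 with an estimated correlation. Mvd, an enzyme of the mevalonate pathway, rose by 0.74 (adjusted p = 0.02). Glycolysis genes were higher (1 of 16 rose, 3 adjusted over the list alone; median 0.14, adjusted p = 0.0219; adjusted p = 0.424 with an estimated correlation), with Pfkl at 0.95 (adjusted p = 0.011). Small shifts downward passed for the myogenic list (1 of 29 fell, 3 fell and 1 rose adjusted over the list alone; median -0.07, adjusted p = 0.0219, and 0.131 with an estimated correlation) and the proteasome list (1 of 35 fell, 1 adjusted over the list alone; median -0.07, adjusted p = 0.0219, and 0.424 with an estimated correlation). A small shift downward also passed for the interferon list (0 of 32 fell, 2 adjusted over the list alone; median -0.09, adjusted p = 0.0221, and 0.424 with an estimated correlation). The calls of the glycolysis, myogenic, proteasome and interferon lists also ended without single cultures. The highest adjusted p then was 0.152 for the myogenic and 0.0674 for the glycolysis list (without culture 3 of D7F), 0.16 for the proteasome list (without culture 1 of WTD) and 0.0717 for the interferon list (without culture 3 of WTD). Single cultures also ended the calls of Pfkl and Mvd (adjusted p = 0.0657 and 0.0935 without culture 1 of WTD) and of Psma1 (-0.53, adjusted p = 0.0337; 0.166 without culture 2 of D7F), which also ended with the culture number as a block.

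**Figure D4:**
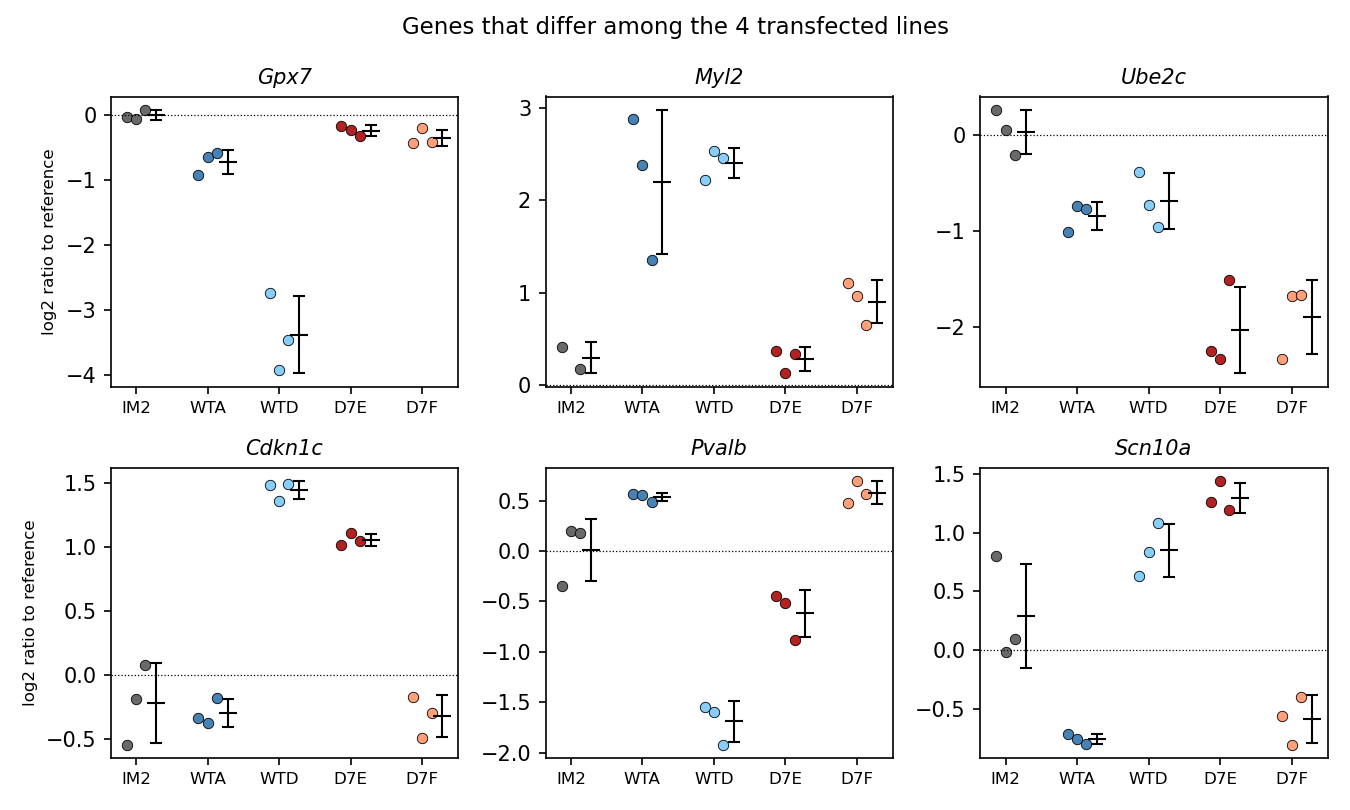
Log2 ratio over the IM2 reference for Gpx7, Myl2, Ube2c, Cdkn1c, Pvalb and Scn10a in each culture, by line. Points are cultures, bars show the mean with its SD, and the dotted line marks a ratio of 1. Gpx7 has its lowest mean, -3.38, in WTD, Myl2 is highest in WTA and WTD (2.20 and 2.40), and Cdkn1c is higher in WTD and D7E (1.45 and 1.06) than in WTA and D7F (-0.30 and -0.32).

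Over both levels, mutant was compared with wild-type Pabpn1 as the mean of D7E and D7F against the mean of WTA and WTD. The mesothelin gene Msln was higher in the mutant lines by 0.70 (SE 0.07, adjusted p = 0.00156) and the matrix protease gene Mmp23 by 0.65 (SE 0.08, adjusted p = 0.00459). Myl2 fell by 1.71 (SE 0.21, adjusted p = 0.00431), Ube2c by 1.20 (-1.20, SE 0.17, adjusted p = 0.00941) and Fxyd1, a regulator of the sodium pump, by 0.91 (-0.91, SE 0.12, adjusted p = 0.00547). The differences of Gpx7 (1.75, SE 0.16, adjusted p = 0.000413) and of a probe of Xlr (-1.62, adjusted p = 0.0043) came mainly from WTD. Gpx7 had means of -3.38 in WTD, -0.72 in WTA, -0.25 in D7E and -0.35 in D7F. The Xlr probe had means of 1.54 in WTD, -0.19 in WTA, -0.83 in D7E and -1.07 in D7F, and a second Xlr probe differed by -0.17. Cell cycle genes were lower in the mutant lines (2 of 50 fell and 0 rose, 8 and 0 adjusted over the list alone; median -0.19, camera, adjusted p = 3.78e-08), with adjusted p = 0.0565 with an estimated correlation. Pola1 was among them (-0.92, adjusted p = 0.0212), a call that ended without any of 6 single cultures (adjusted p up to 0.0762, without culture 2 of WTD) or with the culture number as a block. Ribosomal genes shifted upward (0 of 61 passed singly, 0 adjusted over the list alone; median 0.11, adjusted p = 0.000106; adjusted p = 0.693 with an estimated correlation). So did matrix genes (0 of 54 passed singly, 0 adjusted over the list alone; median 0.10, adjusted p = 0.0131; adjusted p = 0.693 with an estimated correlation). The matrix call ended without culture 1 of WTA (adjusted p = 0.382), culture 2 of WTD or culture 3 of D7E. In total 19 probes passed, 10 higher and 9 lower in the mutant lines, with 650 at an unadjusted p under 0.05 (limma with Benjamini-Hochberg adjustment). With the arrays centred the split was 10 and 15, and with scaling added it was 8 and 17. The 4 lines can be paired in 2 other ways: high against low called 37 probes, and WTD with D7E against WTA with D7F called 230. With the line as a random block, limma called 0 probes. The call of Ube2c ended without the arrays with many values at the limit or missing, and that of Myl2 with the limit values kept. The count was 12 without culture 2 of D7E, 11 without culture 2 or 3 of D7F, and 30 without culture 3 of WTA. It was 10, 11 and 12 without cultures 1, 2 and 3 of WTD, and 10 without the arrays with many values at the limit or missing.

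The lines labelled high were compared with those labelled low as the mean of WTA and D7E against the mean of WTD and D7F. Besides Pabpn1 (0.73), the lysyl oxidase family member Loxl2 was higher in the high lines by 1.76 (SE 0.20, adjusted p = 0.00148) and Actr1a by 1.08 (SE 0.16, adjusted p = 0.0122). Vapb, a membrane protein of the endoplasmic reticulum, was higher by 1.00 (SE 0.10, adjusted p = 0.00148) and the lipolysis activator Abhd5 by 0.71 (SE 0.09, adjusted p = 0.00232). The DNA repair gene Rad51b fell by 1.15 (SE 0.11, adjusted p = 0.00148) and Isg15 by 0.75 (-0.75, SE 0.10, adjusted p = 0.00575). Hif1an (0.97), Pdcd4 (0.85), Tmem176b (-0.56), Usf2 (-0.47), Trim25 (-0.44), Rpl23 (-0.37) and Mocs2 (-0.33) passed as well. A second Rpl23 probe differed by -0.051. Each of these 7 calls ended without single cultures, and those of Pdcd4, Tmem176b, Trim25, Rpl23 and Mocs2 also with the culture number as a block. The highest adjusted p without a culture was 0.0736 for Hif1an and 0.0992 for Pdcd4 (without culture 2 of WTD), 0.105 for Tmem176b, 0.0738 for Usf2 and 0.101 for Mocs2 (without culture 3 of WTD). It was 0.132 for Trim25 (without culture 1 of D7F) and 0.151 for Rpl23 (without culture 1 of WTD). Interferon genes were lower in the high lines (2 of 32 fell and 0 rose, 2 and 0 adjusted over the list alone; median -0.12, camera, adjusted p = 0.00474; adjusted p = 0.55 with an estimated correlation). Cholesterol synthesis genes were higher (0 of 15 passed singly, 0 adjusted over the list alone; median 0.17, adjusted p = 0.0165; adjusted p = 0.55 with an estimated correlation), a call that ended without culture 1 of D7E (adjusted p = 0.0826). Sarcomere genes shifted upward, though not with the arrays centred and scaled (0 of 37 passed singly, 2 rose adjusted over the list alone; median 0.13, adjusted p = 0.00474, and 0.564 with an estimated correlation). So did genes of calcium handling and energy metabolism, again not with the arrays centred and scaled (0 of 26 passed singly, 1 rose and 1 fell adjusted over the list alone; median 0.10, adjusted p = 0.025, and 0.579 with an estimated correlation). Matrix genes shifted downward, but not with the arrays centred and scaled (1 of 54 rose, 7 fell and 1 rose adjusted over the list alone; median -0.14, adjusted p = 0.00474, and 0.579 with an estimated correlation). With that scaling the median was 0.12 (adjusted p = 0.139). Single cultures ended the calcium and energy call (adjusted p up to 0.237, without culture 1 of D7E) and the matrix call (0.182, without culture 1 of WTA). In total 37 probes passed, 20 higher and 17 lower, with 768 at an unadjusted p under 0.05 (limma with Benjamini-Hochberg adjustment). The split was 23 higher and 9 lower with the arrays centred, and 22 and 10 with scaling added. The count was 24 without culture 2 of D7E, 18 and 21 without cultures 1 and 2 of D7F, and 20 and 71 without cultures 1 and 2 of WTA. It was 22, 20 and 20 without cultures 1, 2 and 3 of WTD, 17 without the arrays with many values at the limit or missing, and 4 with the line as a random block. The calls of Vapb and Isg15 ended without the arrays with many values at the limit or missing, and that of Isg15 with the arrays centred and scaled.

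The interaction asked whether mutant and wild-type Pabpn1 differed by another amount at the high than at the low level. It is given as the mean of WTD and D7E minus the mean of WTA and D7F. The interaction of 3830403N18Rik was 2.12 (SE 0.27, adjusted p = 0.000831) and that of Scn10a 1.75 (SE 0.14, adjusted p = 3.37e-05). That of Kcnmb4 was 1.61, that of Cdkn1c 1.56 (SE 0.10, adjusted p = 1.24e-05), that of Padi2 1.50 and that of Tcstv1 1.49 (highest adjusted p = 0.00476). Cdkn1c, for example, had line means of 1.45 in WTD and 1.06 in D7E, against -0.30 in WTA and -0.32 in D7F. Other interactions came mainly from a single line. For 3830403N18Rik the means were 2.35 in WTD, -0.92 in WTA, -1.41 in D7E and -2.37 in D7F. In WTA, WTD, D7E and D7F, Padi2 lay at -1.90, 0.02, 0.61 and -0.46. Tcstv1 lay at -3.19, -1.10, -1.08 and -1.96 in the same order. On the other side, Pvalb had an interaction of -1.71 (SE 0.12, adjusted p = 1.32e-05), Ces2g of -1.51, Gpx7 of -1.27 and Adm of -1.20 (highest adjusted p = 0.00491). That of Gpx7 came mainly from WTD, at -3.38 beside -0.72 in WTA, -0.25 in D7E and -0.35 in D7F. Eml1 (-1.13, adjusted p = 0.0266) and Cav1 (-1.09, adjusted p = 0.0195) passed too, but their calls ended without single cultures, at an adjusted p of up to 0.0824 and 0.0592 without culture 2 of D7F. Glycolysis genes were lower in WTD and D7E (0 of 16 rose and 3 fell, 0 and 4 adjusted over the list alone; median -0.33, camera, adjusted p = 0.000222; adjusted p = 0.337 with an estimated correlation). Pfkl had -0.93 (adjusted p = 0.000447) and Bnip3 -1.03 (adjusted p = 0.00267). Cholesterol synthesis genes were lower there as well (2 of 15 fell, 2 adjusted over the list alone; median -0.37, adjusted p = 0.00288; adjusted p = 0.249 with an estimated correlation), with Mvd at -0.55 and Fdft1 at -0.51 (both adjusted p = 0.00582). Splicing genes (1 of 55 rose, 1 adjusted over the list alone; median 0.08, adjusted p = 0.0213; adjusted p = 0.337 with an estimated correlation) and ribosomal genes (0 of 61 passed singly, 0 adjusted over the list alone; median 0.06, adjusted p = 0.0213; adjusted p = 0.621 with an estimated correlation) shifted slightly upward. Both calls ended without single cultures, at an adjusted p of up to 0.0849 without culture 2 of WTA and 0.249 without culture 3 of WTA. In total 230 probes passed, 82 with a positive and 148 with a negative interaction, with 1388 at an unadjusted p under 0.05 (limma with Benjamini-Hochberg adjustment). The count was 136 with the culture number as a block, and 110 and 125 without cultures 2 and 3 of D7E, and 116 and 96 without cultures 1 and 2 of D7F. It was 145 without culture 3 of WTA, 108 and 117 without cultures 2 and 3 of WTD, and 101 without the arrays with many values at the limit or missing, where the calls of Kcnmb4 and Adm ended.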

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

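The tests of the arrays with many values at the limit or missing, of differences between single lines, of each line against the other 4 and of splits with 2 sides as the only groups were chosen after the results were seen. The tests of other splits of the cultures, of the IM2 cultures' own ratios and of the amount of Pabpn1 were not.

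In 230 probes the difference between mutant and wild-type lines was not the same at the level labelled high as at the level labelled low, by a test of the interaction itself. Given as the mean of WTD and D7E minus the mean of WTA and D7F, it was positive for 3830403N18Rik (2.12), Scn10a (1.75), Kcnmb4 (1.61), Cdkn1c (1.56), Padi2 (1.50) and Tcstv1 (1.49). It was negative for Pvalb (-1.71), Ces2g (-1.51), Gpx7 (-1.27), Adm (-1.20), Eml1 (-1.13) and Cav1 (-1.09). The values of 3830403N18Rik and Gpx7 came mainly from WTD, and those of Padi2 and Tcstv1 mainly from WTA. Among the gene lists the median was 0.078 for splicing and hnRNP proteins, 0.061 for ribosomal proteins, -0.33 for glycolysis and -0.37 for cholesterol synthesis. None of these 4 shifts passed with an estimated correlation between genes (adjusted p = 0.337, 0.621, 0.337 and 0.249). The splicing and ribosomal calls also ended without single cultures, at an adjusted p of up to 0.0849 without culture 2 of WTA and 0.249 without culture 3 of WTA. Outside the probes that could be tested, 2 unnamed part II probes were at the upper limit on 5 of 6 D7F arrays and on 0 IM2 arrays. Both were also at that limit on 1 WTA array, and 1 of them on 1 WTD array. In all, 4 of 9144 untested part II probes were at the upper limit on 5 or more of 6 D7F arrays. At the lower limit there were 5 such probes in D7E and 10 in IM2, although the IM2 arrays compare IM2 with an IM2 reference. Repeated values at a limit therefore also occur where no difference between lines is measured.

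The first pattern is the shift of all 4 transfected lines against IM2 (1479 probes). A departure of the IM2 cultures from the IM2 reference as the whole cause is argued against by the median share of the difference that lay in the transfected lines' own ratios, 0.8963 (quartiles 0.680 and 1.02), although the share was under 0.5 for 236 probes (16.0%). This share depends on the direction of the IM2 arrays, which has no marker, and it was not computed with their sign turned. Without the 10 arrays with many values at the limit or missing, the differences kept a median of 0.9004 of their size and 99.7% of 1453 probes kept their sign. For these probes, most of the difference is thus also present in the remaining arrays. The probes were called with the 10 arrays included, and both estimates share most arrays. This comparison therefore cannot exclude a contribution of the 10 arrays. The number of calls was 502 without them, but there the cultures concerned counted with their other array, and 12170 probes were tested instead of 9703. With as many other arrays of the same lines and parts left out in the same way, 0 of 40 draws gave so few calls (574 to 1706, median 1075.5). On the probes of the main comparison alone, 636 of the 9403 that could still be tested were called without the arrays. There 0 of 40 draws that also lost whole cultures gave so few (652 to 1601, median 1032). The fall in calls may thus come in part from these arrays and in part from having fewer arrays, since the medians of the draws also lie under 1479. A shared effect of Pabpn1, of transfection or of the growth of the transfected lines may each account for the shift, and the design, with no line transfected without Pabpn1, gives no test between them.

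The second pattern is the difference between mutant and wild-type lines (19 probes). Differences between single lines that follow no genotype may account for much of it, since the pairing of WTD with D7E against WTA with D7F gave 230 calls, more than genotype (19) or level (37). For the amount of Pabpn1 as a cause, 8 of the 19 probes differed by genotype and by level with opposite signs (42.1%, exact 95% interval 20.2 to 66.5). The interval treats the probes as independent, which probes measured on the same cultures are not. An effect of the lower Pabpn1 signal in the mutant lines would need opposite signs in most of the 19 probes. The share thus gives no support to this cause, and so few probes cannot exclude it. An effect of the mutation itself stays open and cannot be told apart from differences between the lines, because each genotype and level has 1 line.

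Other splits of the same cultures were counted for each comparison. Nearly all of the 100 splits drawn for transfected against IM2, high against low, the interaction and mutant against wild-type break up lines. A split that keeps the lines whole therefore calls more probes whatever the genotype or level, and these counts show that cultures of 1 line resemble each other. In these counts a split divides each side further into groups of 3 cultures, which are the lines in the real split and mixtures of lines in the others, so the spread within groups changes as well as the sides. The real count and the highest other were 1479 and 39 for transfected against IM2, 37 and 6 for high against low and 230 and 3 for the interaction, with 1 split, the real one, as high in each. For mutant against wild-type 2 of 100 splits gave as many as the real 19. The other, WTA with D7F against WTD with D7E, called 67 against a next highest of 5 with its lines mixed within each side, and calls 230 with the lines as groups. It points to a structure of the cultures by line. With the 2 sides as the only groups, so that all splits had 1 form of model, the real count and the highest other were 1162 and 68 for transfected against IM2, 4 and 139 for mutant against wild-type, 7 and 0 for high against low and 139 and 0 for the interaction. Splits that keep the lines whole are too few for a share under 0.05. By such splits 19, 37 and 230 probes were called for the 3 pairings of the transfected lines. With each line in turn against the mean of the other 4, 1479 were called for IM2, 285 for WTA, 73 for WTD, 102 for D7E and 21 for D7F. For the comparisons of 3 cultures with 3, the 10 splits are too few for a share under 0.05. The real count and the highest other were 1121 and 32 for WTA, 682 and 2 for WTD, 1197 and 8 for D7E and 438 and 21 for D7F, each against IM2. They were 159 and 9 for D7E against WTA and 44 and 1 for D7F against WTD, with 1 split, the real one, as high in each.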

How the results depend on the processing

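The alternatives that kept the values at the limit, left out the arrays with many values at the limit or missing, turned the sign of the IM2 arrays, or joined the titles' dye with 1 orientation alone were chosen after the data were examined, and all others before. No signal over background could be used to judge the arrays. Of 88 list shifts that passed, 7 kept their direction and their side of the threshold in every alternative, and of 365 calls of named genes 107 did. Every count stayed within 1.5 times of the main one with the arrays centred, the adjustment made within each part and the D7F array with the conflicting description left out. The titles' dye for WTA culture 3 cannot change a mean over both orientations. With the mean over all probes of a gene 89 list shifts passed. In the values that follow, the order is WTA, WTD, D7E and D7F against IM2, transfected against IM2, D7E against WTA, D7F against WTD, mutant against wild-type, high against low, interaction, and overlap of all 4 lines, with those named that moved by over 1.5 times. The probes tested were 12858 with Cy3 arrays alone, 12851 with Cy5 arrays alone, 18235 with either orientation enough, 5527 with complete probes only, 12924 with the limit values kept and 12170 without the arrays with many values at the limit or missing, so these settings changed the probes as well. The cause of these moves was not tested, except for the last of these settings in transfected against IM2.

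With the arrays centred and scaled, WTA called 380 probes, WTD 1142 and D7F against WTD 102. Cy3 arrays alone called 590, 291, 477, 236, 837, 37, 14, 5, 9 and 49 probes, with an overlap of 102. Cy5 arrays alone called 290, 219, 420, 101, 699, 10, 16, 5, 7 and 37, with an overlap of 44. With the titles' dye, Cy3 arrays alone called 467 in WTA, 112 in D7E against WTA, 8 for mutant and 6 for high against low, and Cy5 arrays alone 4 in D7E against WTA. With either orientation enough, the counts were 639, 253, 668, 214, 982, 33, 18, 9, 16 and 66, with an overlap of 96. With arrays as units and a dye term, WTA had 1689, WTD 1217, D7F 835, D7E against WTA 554, D7F against WTD 135, mutant 76, high against low 133, the interaction 575 and the overlap 431. With only the lines compared in the fit, the 4 lines had 14, 227, 348 and 83, D7E against WTA 2, D7F against WTD 29 and the overlap 7. Against 0, without the IM2 cultures, the lines had 2475, 1719, 2391 and 1492, their mean 4750 and the overlap 641. With only probes measured in all 15 cultures, D7E against WTA had 375, D7F against WTD 72, mutant 34, high against low 61 and the interaction 436. At an adjusted p under 0.01 the counts were 404, 192, 388, 166, 551, 32, 14, 10, 15 and 64. With the limit values kept, WTA had 677, WTD 383, D7E 755, D7E against WTA 45, D7F against WTD 18, mutant 10, high against low 19 and the interaction 79. Without the arrays with many values at the limit or missing the counts were 413, 198, 333, 137, 502, 48, 23, 10, 17 and 101, with an overlap of 58. With the sign of the IM2 arrays turned, D7F had 708. With the line as a random block, limma called 0 probes for mutant against wild-type, where 650 had an unadjusted p under 0.05 in the fit without it, and 4 for high against low. With an estimated correlation 9 of the 88 list shifts passed. That setting also used a t distribution with fewer degrees of freedom, so the losses need not come from the correlation alone.

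With the replicate number as a block, D7E against WTA had 75 calls and the interaction 136. The block moved no other count by over 1.5 times: it gave 1092, 602, 1125 and 410 for the 4 lines, 1448 for their mean, 34 for D7F against WTD, 13 for mutant against wild-type, 27 for high against low, an overlap of 203 and 88 list shifts. The labels do not say that a number marks a shared day or batch, and over 30 pairs of cultures with the same number the deviations from the line means correlated with a median of -0.00694 (-0.18 to 0.28, 9 over 0.1). Over the 60 other pairs the median was -0.0147. Of 15 cultures, 9 correlated best with those of their own number. Pairs with another number outnumbered those with the same number, 60 to 30, so 9 of 15 leans towards a shared batch. The 2 medians lie close together, however. The number to be found without any pairing was not computed, so these values leave open whether a number marks a shared batch. The main fits do not use the numbers, and the counts with the block stand beside them.

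With each culture left out in turn, the counts ranged from 581 to 1343 for WTA, 297 to 1038 for WTD, 768 to 1443 for D7E, 207 to 762 for D7F, 802 to 1669 for their mean, 50 to 158 for D7E against WTA, 15 to 56 for D7F against WTD, 10 to 30 for mutant against wild-type, 18 to 71 for high against low and 96 to 229 for the interaction. The overlap ranged from 125 to 475 and the list shifts from 82 to 91.

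With the sign of the IM2 arrays turned, these differences from IM2 changed sign, with only Trabd (adjusted p = 0.000381) and Scd1 (adjusted p = 0.0246) past the threshold in the new direction: Tcte3 (-0.17), Snrpb (-0.77), Ptges3 (-0.010) and Scd1 (-1.92) in WTA, Trabd in WTD (-1.78), Snrpb in D7E (-1.13) and D7F (-0.96), Actr1a in the mean of the lines (-0.0026), and the median of the heat shock list in WTA (-0.010) and WTD (-0.038). Scd1 in WTA was -0.037 against 0 without the IM2 cultures, and Mef2c in D7E was -0.74 with the limit values kept. With the arrays centred and scaled, the high against low shifts of the sarcomere list (median -0.0014), the calcium and energy list (median 0.035, with the test pointing down) and the matrix list (median 0.12) were lost, with the test pointing the other way (adjusted p = 0.749, 0.749 and 0.139). The cause was not tested.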

Other observations

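The list of genes induced by low oxygen or low nutrients and its test were chosen after Ndrg1, Adm, Ero1a and Fam162a had been seen, and the prediction was written before the remaining members were examined.

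Several genes known to be induced when cells run short of oxygen were lower in the transfected lines than in IM2, beyond those named so far. Angptl4, a secreted inhibitor of lipoprotein lipase, fell by 1.36 on the log2 scale (SE 0.18, adjusted p = 0.000605, limma with Benjamini-Hochberg adjustment), and Hilpda, a lipid droplet protein, fell by 1.47 (SE 0.21, adjusted p = 0.00186). The circadian regulator Bhlhe40 fell by 0.90 (adjusted p = 0.00385), Mxi1 by 0.57 (-0.57, adjusted p = 0.0022) and Egln1, an oxygen-sensing prolyl hydroxylase, by 0.67 (-0.67, adjusted p = 0.0246). Plin2 rose by 0.74 (adjusted p = 0.0303), and Higd1a (-0.60, adjusted p = 0.0929), Gbe1 (-0.58, adjusted p = 0.0819) and Kdm3a (0.11, adjusted p = 0.83) did not pass. These are the 9 measured members of the list that lie on no fixed list and had not been seen when the list was chosen. They are named here after their values were seen. Of all 23 measured members, 16 fell, 1 rose and 6 did not pass. The 6 include Slc2a1 (0.79, adjusted p = 0.141), Asns (0.10, adjusted p = 0.776) and Chac1 (-0.35, adjusted p = 0.16), which lie on fixed lists.

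A hypothesis is that the IM2 cultures and the IM2 reference, which share their line, were short of oxygen or nutrients relative to the transfected cultures, for example because they had grown denser. These 9 members shifted down (camera p = 0.000292 with the preset correlation of 0.01, median -0.60, 5 fell, 1 rose and 3 did not pass). No estimated correlation was used for this list, and with it only 9 of the 88 shifts of the fixed lists passed. Since the list was written around genes already seen to fall, a shift in this direction is weak support. Such a difference in culture conditions may contribute to the shift of the transfected lines. A change of the same genes by Pabpn1 or by transfection would give the same values and was not tested apart. The labels give no cell density or medium.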
